A study of Mus musculus with 6 samples.

How the data were processed

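Total RNA was sequenced from mouse CD4 T cells of wild type (WT) mice and of mice in which Yap1 is deleted in T cells (YAP cKO, a floxed Yap1 allele recombined by Cre under the CD4 promoter). YAP is a transcriptional co-activator of the Hippo pathway that acts through TEAD factors. Per the labels' protocols, naive CD4 T cells (CD25-) and natural regulatory T cells (nTregs, CD4+ CD25 high) were flow sorted from lymph nodes and spleens of C57BL/6 animals. Some nTregs were stimulated with plate-bound anti-CD3 at 2 µg/ml, soluble anti-CD28 at 2 µg/ml and IL-2 at 100 U/ml. The treatment text gives 24 h of stimulation and the extraction text gives 48 h, so the time is not settled by the labels. The design holds 6 libraries: WT and cKO for each of the 3 populations naive CD4 T, fresh nTreg and stimulated nTreg, with 1 library per group. The labels do not state how many mice stand behind a library.

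Per the labels' protocols, strand-specific libraries were made from 322 ng of total RNA after depletion of ribosomal RNA, with 12 PCR cycles, and sequenced on an Illumina HiSeq2000. Per the submitters' processing notes, reads were checked with FastQC, aligned to mm10 with TopHat and quantified with Cuffdiff and Cuffnorm, with no versions given. The deposited values are FPKM (fragments per kilobase of transcript, scaled by mapped fragments), which the authors computed per RefSeq transcript and scaled across the 6 libraries with Cuffnorm. FPKM depends on the transcript length and on the other RNA in the library and carries no counts, so no count model was used. The value columns carry the abbreviation YKP for one genotype, and these were read as the YAP cKO libraries by elimination, since the other columns are named WT. All directions between genotypes rest on those column names, because Yap1 gave no support for them. It is listed at 0 in the naive and fresh nTreg libraries, and in stimulated nTregs it was higher in the column read as cKO (0.235 against 0.169 FPKM), from few fragments on exons that are not recorded.

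The deposited table held 32860 rows for 32547 transcripts, and the 165 transcripts listed in more than 1 row had identical values in each and were counted once. Transcripts were named with the reference annotation (GRCm38), which named 32101 of them, and the deposited symbol named a further 397, while 49 had no symbol. Summing the FPKM of each gene's transcripts gave 24011 genes. Short features (small nucleolar, small nuclear and micro RNA, and segments of antigen receptors) held 36.4% and 36.6% of the FPKM sum in the WT and cKO naive libraries, 37.1% and 36.6% in the fresh nTreg libraries, and 16.3% and 18.1% in the stimulated nTreg libraries. The FPKM sums were 968967 and 962865 in naive, 837179 and 843887 in fresh and 534274 and 595524 in stimulated cells, WT first.

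Library totals were not used here, so the worth of 1 fragment was read from the steps between the lowest values of single-transcript genes. On a transcript of 1 kb, 1 fragment was worth about 0.135 FPKM in WT naive, 0.115 in cKO naive, 0.109 in WT fresh, 0.115 in cKO fresh, 0.142 in WT stimulated and 0.109 in cKO stimulated. Between 97.7% and 100% of the low values used (0.005 to 0.06 FPKM) were ratios of whole fragments within a log2 tolerance of 0.02. These depths are estimates and cover counting error only, since PCR copies were not marked. In 100 Poisson simulations at these depths with no difference between genotypes, counting alone placed on average 5.05 genes at least 2-fold apart in naive cells, 2.63 in fresh nTregs and 5.62 in stimulated nTregs.

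Within each population the cKO library was compared with the WT library as the difference of log2(FPKM + 1), which understates the fold of genes with low FPKM. Genes with FPKM of at least 1 in 1 or both libraries were compared, and those at least 2-fold apart were counted without a p-value. The difference of the stimulation response was computed the same way, as the cKO change from fresh to stimulated minus the WT change. For effects shared across libraries, limma was fitted to log2(FPKM + 1) with an additive model of population and genotype, an intensity trend and moderated variances, over 11224 genes with FPKM of at least 1 in at least 2 libraries. That model leaves 2 residual degrees of freedom, with 4.02 prior degrees of freedom, and its error is the spread of the genotype difference over the 3 populations. The p-values therefore measure spread between libraries and populations, not between mice. They were adjusted with Benjamini-Hochberg, and an adjusted p under 0.05 was called.

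A total of 28 gene lists were fixed before the data were examined. The T cell lists were Hippo pathway components, YAP-TEAD target genes, TGF-beta and activin signalling, Treg signature, naive and quiescent T cell, TCR-induced activation, cytokines, helper lineage, checkpoint receptors and trafficking receptors. The state lists were IL-2 and STAT5 response, proliferation, glycolysis, cholesterol synthesis, interferon response, NF-kappaB response, apoptosis regulators, unfolded protein and amino acid response, immediate early and sorting stress and nuclear-retained RNA. The others were markers of B cells, of myeloid and dendritic cells, of CD8 T cells, of NK and cytotoxic cells, of erythroid cells, of platelets and of stromal and endothelial cells, and sex-linked genes. Ighm, Ighd, Hbb-bt and Ahsp were not found in the table. In the single-library comparisons each list's median log2 difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, which is a description and no test. In the additive model, members past the threshold were counted over all genes and adjusted over the list alone. The 25 lists with at least 2 measured members were also tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. The estimated version rests on the 2 residual degrees of freedom, so a list can hardly pass it. A list that does not pass it is therefore not shown to be unchanged. The preset version takes the members as nearly independent, so its p-values are too small for a list whose members vary together. The comparisons, tests, lists, naming rule and most alternatives were also chosen before the data were examined.

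The naming rule took Yap1, Foxp3 and Il2ra, then the 10 largest rises and 10 largest falls of each genotype comparison with FPKM of at least 5 in the higher library. It also took the 10 largest called rises and falls of each limma contrast with FPKM of at least 5 in a library, the 5 largest response differences each way, and up to 4 members per list and comparison. Predicted genes with Gm or Rik symbols, small RNAs, receptor segments and joined symbols were counted but not named. Near copies of named and called genes were searched with BLAST among all annotated transcripts, at 95% identity over at least 50% of the transcript. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and BLAST 2.17.0.

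The limma model was tested on simulated data of the same size, in 20 simulations with 100 genes changed 2-fold and 100 changed 4-fold. Their noise was normal and took each gene's moderated variance. The model recovered 98.8% of the 2-fold genotype changes, 96.2% of those between fresh nTreg and naive cells and 96.5% of those with stimulation, and 7.68%, 6.91% and 7.98% of its calls were false. Moderated variances differ less between genes than real ones, so these shares do not give the recovery in the real data. For 200 simulated lists of 20 genes in stimulated nTregs, 7% fell outside the middle 95% of random lists with no shift and 99.5% did with a shift of 0.5 in log2. The simulated genes varied independently, so lists whose members vary together can fall outside that range more often without a genotype effect. Alternatives were a pseudocount of 0.1 or 5, no FPKM minimum or a minimum of 5, rescaling by the median of ratios or to an equal FPKM sum per library, and a 3-fold threshold. For the model they were also limma without a trend or with robust moderation, leaving out each library, and removing short features. Leaving transcripts unsummed, and removing short features in the single-library comparisons, were alternatives chosen after the data were seen. No library was left out of the main results.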

Results

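The data are 6 total RNA libraries of mouse CD4 T cells, WT and YAP cKO, from naive CD4 T cells, freshly sorted nTregs and nTregs stimulated through the T cell receptor with IL-2. Each group has 1 library and no replicates, so differences between genotypes within a population are values without a test. Between 10210 and 10893 genes per library had FPKM of at least 1. A gene at 5 FPKM with a 2 kb transcript stood on about 70.7 fragments in the shallowest library, WT stimulated nTreg, and on about 92.0 in the deepest, WT fresh nTreg.

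Yap1 (mm10 chromosome 9, 7931999 to 8004638) was listed at 0 FPKM in the WT and cKO libraries of naive cells and of fresh nTregs. It was 0.169 in WT stimulated nTregs and 0.235 in cKO stimulated nTregs. A count of 3 fragments on its 4171 nt transcript would give 0.0782 to 0.102 FPKM across the libraries, so a loss of Yap1 RNA could not be seen in the 4 libraries at 0. The stimulated nTreg libraries lay above that level, at about 4.99 fragments in WT and 8.98 in cKO. Yap1 was not lower in the library labelled cKO. Fewer genes were listed at 0 in the stimulated libraries (4122 in WT and 4872 in cKO) than in fresh nTregs (9312 and 9110). Trace values were thus more common after stimulation, and whether the Yap1 fragments are more than that was not tested. Which exons these fragments cover is not recorded. The identity genes followed the sorts: Foxp3 (chromosome X, 7579676 to 7595243), the lineage factor of Tregs, was 46.6 and 45.9 FPKM in WT and cKO fresh nTregs and 56.9 and 57.8 after stimulation, against 2.98 and 3.30 in naive cells. The Foxp3 transcript that held 44.8 FPKM in WT fresh nTregs was at 0.000307 in WT naive and 0.435 in cKO naive cells. Il2ra (chromosome 2, 11642792 to 11693194), which encodes CD25, was 0.486 and 1.23 in naive cells, 75.3 and 63.7 in fresh nTregs and 295 and 285 in stimulated nTregs.

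**Figure D1:**
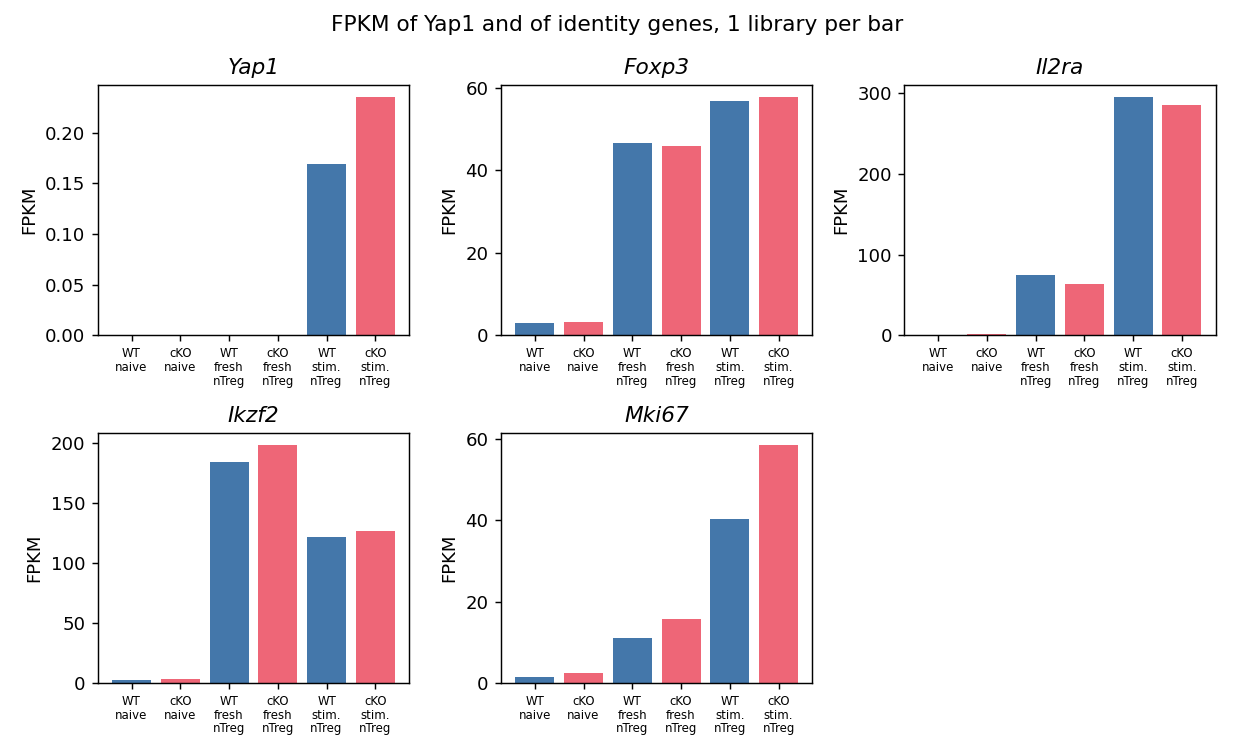
FPKM (y axes, each from 0) of Yap1, Foxp3, Il2ra, Ikzf2 and Mki67 in the 6 libraries, 1 bar per library, WT in blue and cKO in red, with no error bars because each group has 1 library. Yap1 is listed at 0 outside the stimulated nTregs, where it is 0.169 in WT and 0.235 in cKO, and Ikzf2 stands at 2.77 and 3.47 in naive cells against 184 and 199 in fresh nTregs.

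In naive CD4 T cells, the cKO library had more RNA of interferon-response genes and less of NK and cytotoxic markers than the WT library. The interferon list had a median log2 difference of 0.50, above all 10000 random lists, and 19 of 22 members were higher in cKO. Among them were the antiviral genes Rsad2 (3.76 to 8.97 FPKM), Isg15 (11.3 to 23.9), Ifit3 (17.7 to 34.7) and Mx1 (3.86 to 8.04). The 6 measured NK and cytotoxic markers were all lower in cKO, with a median of -0.46 at percentile 0.01 of random lists. Gzma, a granzyme, was 4.96 in WT and 1.24 in cKO. All 10 measured members of the IL-2 and STAT5 response list were higher in cKO (median 0.22), as were 11 of 13 immediate early and sorting stress genes (median 0.18). The cholesterol synthesis list (median 0.16, 14 of 20 higher) and the TCR-induced activation list (median 0.15, 10 of 19 higher) also lay above the random range. The TCR-induced activation median turned to -0.03 at an FPKM minimum of 5. The 7 measured YAP-TEAD target genes had a median of -0.17, at percentile 1.31 of random lists. Dock5 stood at -0.27 and Nt5e, the ectonucleotidase CD73, at -0.24, and none was 2-fold apart. The naive and quiescent T cell list lay slightly above the random range (median 0.08, 10 of 17 higher). No member of the Hippo pathway list was 2-fold apart.

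Across all genes in naive cells, 69 of 10440 were at least 2-fold higher in cKO and 56 were at least 2-fold lower, while 95.9% were within 1.5-fold. The largest differences upward among the genes that the naming rule covers were the pseudogene Ndufs5-ps (0.791 to 18.1 FPKM), Pstpip2 (0.805 to 15.1), an adaptor of the actin cytoskeleton, H60b (0.831 to 14.8), a ligand of the NKG2D receptor, and Eno1b (3.66 to 27.4). Next came the core histone genes H2bc13 (2.05 in log2) and H2ac4 (1.56 to 8.27), Rab4a (2.30 to 9.81), Erdr1 (40.5 to 127) and Jaml (3.11 to 10.9). Actr3b was listed at 0 in WT and was 5.84 in cKO. The largest downward under that rule were Amd1 (15.4 to 0.0408), the nucleoside transporter genes Slc28a2b (48.8 to 5.95) and Slc28a2 (56.6 to 17.4), Tanc1 (9.62 to 1.20) and Cpm (14.8 to 2.79). Smaller values also stood in cKO for H4c11 (8.22 to 1.56), Map7 (8.53 to 1.86), the pseudogene Atp6v0c-ps2 (27.1 to 8.66), Rab20 (5.42 to 1.40), and the transcription factor Klf9 (6.78 to 2.16). Eno1b and Amd1 have near-identical copies. The summed FPKM of Amd1 with Amd2 differed by 0.06 in log2, so in naive cells Amd2 made up the Amd1 difference. That of Eno1 with Eno1b differed by 0.05. Eno1b was only 3.66 and 27.4 of sums of 174.55 and 180.59 FPKM, so this sum cannot show whether fragments were shared differently between the copies. The sums over copies and the gene Casp1 were chosen after their values were seen.

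In fresh nTregs, the medians of the proliferation, helper lineage and trafficking lists were higher in the cKO library, and B cell markers were lower. The proliferation list had a median of 0.32, above all random lists, and 23 of 25 members were higher in cKO. Among them were Ccnb1 (1.02 to 3.38 FPKM), the mitotic cyclin, Top2a (10.8 to 19.0) and Cdc20 (2.00 to 4.03). In the helper lineage list (median 0.20, 9 of 12 higher), Tbx21, the Th1 factor T-bet, was 2.71 in WT and 6.74 in cKO. In the trafficking list (median 0.16, 13 of 20 higher), Ccr2 was 23.3 in WT and 50.2 in cKO. The cytokine list (median 0.20, 7 of 11 higher) held Ccl4 (1.08 and 2.96) and Ifng (17.7 and 33.2). The median of the cytokines turned to -0.02 at an FPKM minimum of 5. The cholesterol synthesis list (median 0.17, 18 of 20 higher), the apoptosis regulators (median 0.14), the immediate early and sorting stress genes (median 0.13, with Hspa1a at 1.26) and the interferon list (median 0.11) also lay above the random range. The naive and quiescent T cell list lay below it (median -0.11, 13 of 17 lower, with Il7r at -0.70), as did the 4 measured nuclear-retained RNAs (median -0.19), of which Xist is 1. The 6 measured B cell markers lay below it too (median -0.38), with H2-Aa 3.14 in WT and 0.985 in cKO. The Treg signature was close to even (median 0.04, 16 of 30 higher), although the granzyme gene Gzmb was 9.80 in WT and 42.9 in cKO. The 8 measured YAP-TEAD target genes had a median of -0.14, at percentile 2.67 of random lists. Nuak2 stood at -0.31 and Crim1 at -0.25, and none was 2-fold apart.

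In the same comparison of fresh nTregs, 69 of 10889 genes were at least 2-fold higher in cKO and 43 were at least 2-fold lower, while 96.1% were within 1.5-fold. Dcpp1 and Dcpp2, genes of secreted proteins of the demilune cell and parotid family, were listed at 0 in WT and were 14.8 and 59.6 in cKO, and neither exceeded 0.476 in any other library. Other genes higher in cKO were Ndufs5-ps (0.647 to 11.9 FPKM), Pstpip2 (1.89 to 14.4), H60b (2.82 to 17.2) and H4c9 (9.25 to 43.3). Among the genes lower in cKO, Xist (chromosome X, 103460373 to 103483233), the RNA that silences 1 X chromosome in female cells, was 30.0 in WT and 3.21 in cKO. In the sex-linked list the other 4 measured members, which lie on the Y chromosome, were all higher in cKO, with Ddx3y at 59.8 and 79.0. Also lower were Snhg9 (25.8 to 3.83), the inflammatory caspase gene Casp4 (28.0 to 6.73), Hmgn3 (8.85 to 1.86), Rab6b (7.52 to 1.59), Jmjd7 (6.80 to 1.91) and Unc5cl (6.47 to 1.86). Eif3j2 (39.1 to 10.2) is a near copy of Eif3j1 (0.145 to 24.0) with the opposite difference, and their sum differed by -0.20. Ndufs5 (16.3 to 4.37) is a near copy of Ndufs5-ps over 60.8% of its transcript, and their sum differed by -0.05 here, 0.60 in naive cells and 1.64 in stimulated nTregs.

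In stimulated nTregs, the medians of the proliferation, cytokine, helper lineage and glycolysis lists were higher in the cKO library, and that of the naive list was lower. The proliferation list had a median of 0.56, above all random lists, and 24 of 25 members were higher in cKO. Among them were Cdc20 (6.73 to 15.1 FPKM), Aurkb (5.10 to 11.1), Top2a (57.3 to 105) and Cdk1 (0.85 in log2). The cytokine list (median 0.53, above all random lists, 8 of 11 higher) held Ccl4 (1.77 in log2), Ifng (4.02 to 15.6), Ccl3 (21.5 to 54.9) and Il10 (0.93 in log2). In the helper lineage list (median 0.39, 8 of 13 higher and 5 lower) Tbx21 was 3.49 in WT and 10.6 in cKO. In the trafficking list (median 0.22) Cxcr6 was 55.6 in WT and 122 in cKO. The 5 measured NK and cytotoxic markers were all higher in cKO (median 0.40), with Nkg7 at 19.9 and 63.7. Glycolysis genes (median 0.38, 15 of 16 higher, with the lactate exporter Slc16a3 at 5.49 and 11.2) and cholesterol synthesis genes (median 0.33, 20 of 20 higher, with Mvk at 1.44 and 3.13) also lay above the random range. So did interferon-response genes (median 0.40, 12 of 17 higher, with Isg15 at 1.38 and 6.78), apoptosis regulators (median 0.30) and checkpoint receptors (median 0.27, 9 of 11 higher, with Lag3 at 4.97 and 10.7). The naive and quiescent T cell list had a median of -0.18, with 14 of 16 members lower in cKO, among them Lef1 (-0.44) and Satb1 (-0.42). The 4 measured nuclear-retained RNAs were all lower (median -0.38), with Xist at -2.32 and Malat1 at -0.35. The Treg signature (median 0.20, 21 of 30 higher), the unfolded protein and amino acid response (median 0.23), the immediate early genes (median 0.19), the YAP-TEAD target genes (median 0.06) and the TGF-beta and activin list (median 0.00) lay inside the random range. In the activin list, the receptor gene Acvr1c (chromosome 2, 58267453 to 58357896) was 3.29 in WT and 1.47 in cKO. Fst, which encodes the activin antagonist follistatin, was 0.680 and 3.15. It was the only member at least 2-fold apart in FPKM + 1, where Acvr1c stood at -0.79 in log2.

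Over all genes in stimulated nTregs, 134 of 11105 were at least 2-fold higher in cKO and 77 were at least 2-fold lower, while 91.9% were within 1.5-fold. The counts depended on the scaling. Rescaled to an equal FPKM sum per library, 143 were higher and 330 lower, and the median over all genes moved from 0.04 to -0.12 in log2. The proliferation list still lay at 0.41 under that scaling, the cytokine list at 0.38 and the naive list at -0.34. Medians inside the random range changed sign under it, with the YAP-TEAD target genes at -0.06 and the NF-kappaB list at -0.09. Genes higher in cKO included Ndufs5-ps (1.23 to 23.7 FPKM), Pstpip2 (5.96 to 33.1), H2bc13 (17.7 to 112), H4c9 (7.60 to 76.7) and H2bc22 (3.33 to 36.3). Eif3j1, Amd1 and Rps27 were also higher but share sequence with a copy, and the sum of Rps27 with Rps27rt differed by 0.20. Genes lower in cKO included Casp4 (23.1 to 3.37), the neighbouring caspase gene Casp1 (18.0 to 6.10), Xist (21.1 to 3.43) and Jmjd7 (-2.16 in log2). Others were Hmgn3 (10.1 to 2.47), Rab6b (8.33 to 2.15), the receptor gene Gpr34 (22.1 to 8.57) and Insl3 (8.27 to 2.12), whose annotated transcript overlaps Jak3. Defa4 was 5.11 in WT and listed at 0 in cKO.

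**Figure D2:**
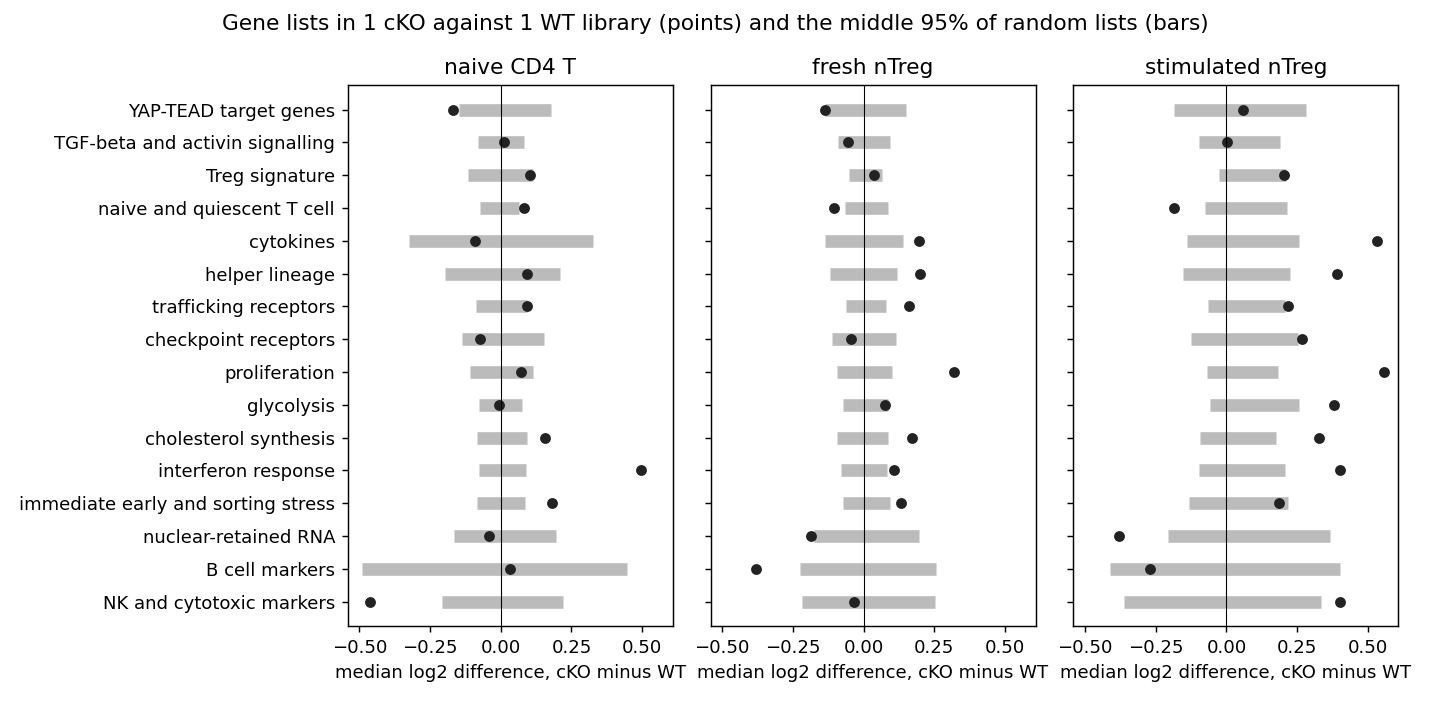
Median log2 difference of 16 fixed gene lists, cKO minus WT, in naive CD4 T cells, fresh nTregs and stimulated nTregs (x axes, log2 of FPKM + 1), with 1 library per genotype. Points are the lists and grey bars the middle 95% of 10000 random lists of the same size and expression; the proliferation list stands at 0.07, 0.32 and 0.56 and the interferon list at 0.50, 0.11 and 0.40.

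Markers of other cells were compared in the same libraries as signs of the purity of the sorts. None of the 8 erythroid markers found was measured at 1 FPKM. The myeloid and dendritic list had medians of 0.04, 0.10 and 0.20 in naive, fresh and stimulated cells, all inside the random range, with Lyz2 at -1.46 in naive cells and -1.17 in fresh nTregs. The CD8 T cell list had 1 measured member, Cd8b1, at 0.14, 0.05 and 0.17. The platelet list had medians of 0.20, 0.10 and 0.12 (the last -0.11 at an equal FPKM sum per library), and the stromal and endothelial list had 1 measured member, Pecam1, at 0.16, -0.01 and -0.19. B cell markers had medians of 0.03, -0.38 and -0.27, of which only that of fresh nTregs lay outside the random range. At an equal FPKM sum per library the medians of fresh and stimulated nTregs were -0.24 and -0.07, the latter above the median of all genes (-0.12). At an FPKM minimum of 5 the B cell markers, median log2 difference, genotype difference in stimulated nTregs, stood at 0.47, which is the value of Cd74 alone. The NF-kappaB response list was inside the random range in all 3 populations, with medians of 0.08, 0.04 and 0.06.

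Across the 3 populations, 29 genes rose and 13 fell with the cKO genotype in the additive limma model, of 11224 tested, and 1346 had an unadjusted p under 0.05. Among the genes that the naming rule covers, the largest rise in log2 was that of Ndufs5-ps, by 3.29 (SE 0.13, adjusted p = 0.000679). Next were H60b (chromosome 10, 22273474 to 22288849), by 2.64 (SE 0.17, adjusted p = 0.00777), and Pstpip2 (chromosome 18, 77794550 to 77882879), by 2.62 (SE 0.18, adjusted p = 0.00777). They were followed by Eno1b, by 2.60 (SE 0.10, adjusted p = 0.000679), and H2bc13, by 2.14 (SE 0.15, adjusted p = 0.00914). The sum of Eno1 with Eno1b differed by 0.05, 0.04 and 0.35 in naive, fresh and stimulated cells. As Eno1 makes up most of that sum in naive cells, it cannot show how much of the Eno1b rise came from fragments shared between the copies. Mid1, a ubiquitin ligase gene on the X chromosome, rose by 1.63, H2bc12 by 1.61 and the class Ib histocompatibility gene H2-T10 by 1.58. Erdr1 rose by 1.48 and Sytl1, a gene of vesicle traffic, by 1.27, each higher in cKO in 3 of 3 populations. The largest falls under that rule were Casp4 (chromosome 9, 5308849 to 5336791), which fell by 1.93 (SE 0.20, adjusted p = 0.0300), and Jmjd7, which fell by 1.61 (SE 0.19, adjusted p = 0.0433). Rab6b fell by 1.58 (SE 0.11, adjusted p = 0.00777) and Slc28a2 fell by 1.36 (SE 0.12, adjusted p = 0.0184). Unc5cl fell by 1.18, Gt(ROSA)26Sor by 0.87, the glutathione transferase gene Mgst2 by 0.84, H2bc15 by 0.57 and Oip5os1 by 0.49, each lower in cKO in 3 of 3 populations. Of 41 called genes that could be searched, 14 have a near copy among the transcripts of other annotated genes, among them Eno1b, H2bc13, Erdr1, Jmjd7 and Slc28a2. The positions of the copies were not compared, so another gene annotated over the same stretch counts as a copy too. Ndufs5-ps could not be searched but is itself a near copy of Ndufs5. The sum of the pair differed by 0.60, -0.05 and 1.64 in naive, fresh and stimulated cells, less than Ndufs5-ps alone. The sum of Slc28a2 with its near copy Slc28a2b differed by -2.13, -1.44 and -0.82 in the same order, so the fall remained in that sum.

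The call of the shared genotype genes leaned on the fresh nTreg libraries. Leaving out either library of a population gives the same genotype estimate, since the model fits the remaining library exactly. The 6 leave-outs are therefore 3 checks, 1 per population. Without the WT fresh nTreg library 14 genes were called, 11 of them among the 42. Without the cKO fresh nTreg library 16 were called, 13 of them among the 42. H60b, Pstpip2, Eno1b, H2bc13, Mid1, H2-T10, Erdr1 and Sytl1 kept their calls whichever library was left out, as did Ndufs5-ps. Casp4, Jmjd7, Slc28a2, Mgst2 and Gt(ROSA)26Sor lost theirs without either fresh nTreg library, and Rab6b without the WT fresh nTreg library. H2bc12 also lost its call without either stimulated nTreg library, Unc5cl without either naive library, and H2bc15 and Oip5os1 whichever of the 6 was left out. With no FPKM minimum, 21218 genes were tested and 4 were called.

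**Figure D3:**
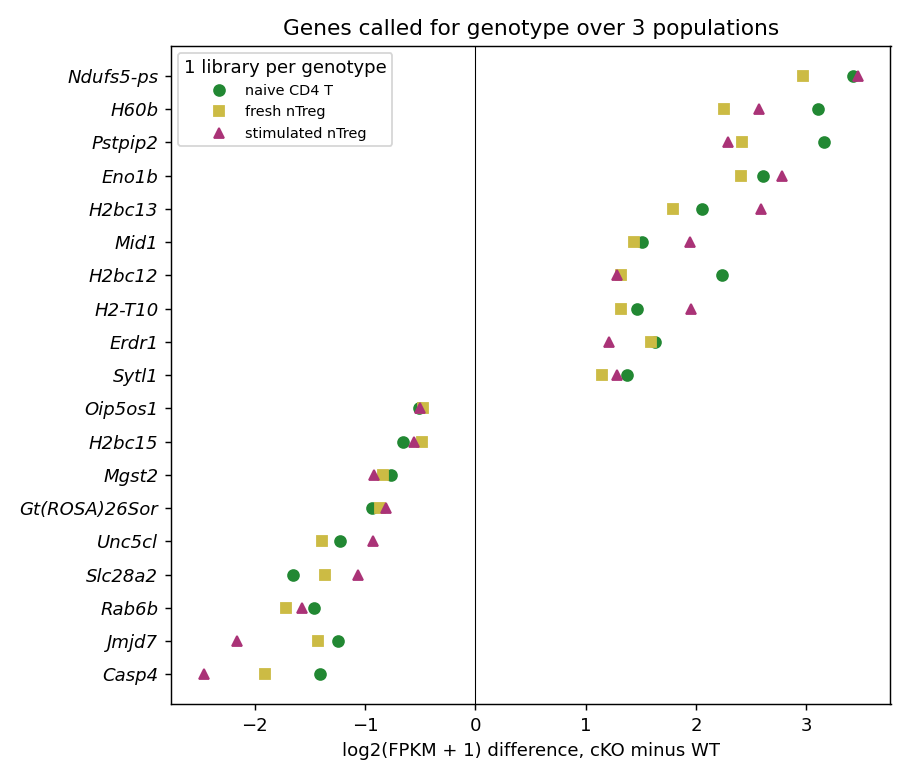
Difference of log2(FPKM + 1), cKO minus WT (x axis), of the 19 named genes called for genotype, in naive CD4 T cells (circles), fresh nTregs (squares) and stimulated nTregs (triangles), with 1 library per genotype behind each point. Each gene lies on the same side of 0 in the 3 populations, with Pstpip2 at 3.16, 2.42 and 2.29 and Casp4 at -1.40, -1.91 and -2.46.

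By size alone, 17 genes were at least 2-fold higher in cKO in all 3 populations and 7 were at least 2-fold lower, where independent differences would give 0.00466 and 0.00135. With 1 population reversed, the micro RNA genes Mir6363 and Mir8104, named after their values were seen, were the 2 genes 2-fold apart in all 3. Over genes, which are not independent replicates, the genotype differences had a Pearson r of 0.22 between naive cells and fresh nTregs, 0.14 between naive cells and stimulated nTregs and 0.21 between fresh and stimulated nTregs. Among the 12 expressed genes within 5 Mb of Yap1, the median absolute difference lay at percentile 97.0 of random lists in naive cells, 93.1 in fresh nTregs and 8.97 in stimulated nTregs. At least 2-fold lower there were Casp1 (chromosome 9, 5298517 to 5307281) and Casp4 in naive cells and stimulated nTregs, and Casp4 alone in fresh nTregs, where Casp1 stood at -0.53.

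Fixed lists in the shared genotype effect held few called members. The proliferation list had a median of 0.33 in log2, with 1 member called over all genes, Top2a, which rose by 0.72 (SE 0.0859, adjusted p = 0.0433), and 7 called adjusted over the list alone. Top2a was not called without either fresh nTreg library or without either stimulated nTreg library. Camera at the preset correlation gave an adjusted p of 4.54e-08 for proliferation, and adjusted p = 0.481 with an estimated correlation. The cholesterol synthesis list (median 0.23, with Idi1 at 0.38 and Fdps at 0.38) had 0 called over all genes and 3 adjusted over the list alone. Its camera test gave an adjusted p of 1.77e-06 at the preset correlation and adjusted p = 0.481 with an estimated correlation. The interferon list (median 0.26, with Isg15 at 1.08 and Ifit3 at 0.69) had 0 called over all genes, and 4 higher and 1 lower adjusted over the list alone. Its adjusted p were 0.000833 and 0.481 for the preset and the estimated correlation. The interferon median was 0.12 without either naive library. Without either stimulated nTreg library the proliferation median was 0.16 and the cholesterol synthesis median 0.14. The Treg signature (adjusted p = 0.0182) and glycolysis (0.0182) passed upward at the preset correlation, as did immediate early genes (0.00274), helper lineage (0.0400), trafficking receptors (0.0400) and TCR-induced activation (0.04995). With an estimated correlation these had adjusted p of 0.565 for glycolysis and 0.481 for the other 5. Naive and quiescent genes (0.0400), Hippo pathway components (0.0439, with the kinase gene Stk3 at -0.44 and Lats2 at -0.24), nuclear-retained RNA (0.0218, with Xist at -1.89 and Malat1 at -0.20) and B cell markers (0.04995) passed downward at the preset correlation. With an estimated correlation naive genes had adjusted p = 0.565 and the other 3 had 0.481, and none of the 25 lists passed. That version could hardly call any list with so few residual degrees of freedom. In fresh nTregs against naive cells the Treg signature, with 30 of 30 members called, had adjusted p = 0.226 by it. The YAP-TEAD target genes (median -0.14, 0 of 9 called over all genes and 0 adjusted over the list alone) did not pass at either correlation, with adjusted p of 0.151 and 0.481. Their median was -0.08 without either naive library and -0.05 without either fresh nTreg library.

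Fresh nTregs differed from naive CD4 T cells first in the genes of the Treg programme. All 30 members of the Treg signature rose in nTregs, over all genes and adjusted over the list alone, by a median of 3.97 in log2. Ikzf2, which encodes the transcription factor Helios, rose by 5.55 (SE 0.0825, adjusted p = 4.81e-06) and Il2ra by 5.27. Lrrc32, the cell surface carrier of latent TGF-beta, rose by 5.25, Itgae by 5.18 and Il10 by 5.02. Foxp3 rose by 3.51 (SE 0.0856, adjusted p = 9.52e-06). Areg was listed at 0 in both naive libraries and was 30.6 and 30.2 FPKM in nTregs. Of the naive and quiescent T cell list, 15 of 17 fell (16 adjusted over the list alone), among them Dapl1 by 3.65, Igfbp4 by 2.63 and Lef1 by 1.64. Foxo1 did not pass over all genes. Receptors and helper genes rose as well, with 14 of 20 trafficking receptors (Ccr2 by 4.66, Cxcr3 by 3.81) and 10 of 13 helper lineage genes (Il1rl1 by 4.21, Maf by 3.45). So did 9 of 11 checkpoint receptors (Ctla4 by 4.01, Pdcd1 by 3.51) and 9 of 11 cytokines (Ifng by 3.52). The rises had the same counts adjusted over the list alone, and S1pr1, Ccr7 and Vsir fell. Adjusted over the list alone, trafficking receptors had 4 falls rather than 2 and the helper list 1 rather than 0. Of the TCR-induced list 13 of 19 rose (Tnfrsf9 by 3.84, Cd44 by 2.45) and Cd40lg fell by 1.68. Of the proliferation list 11 of 25 rose (Mki67 by 2.26), and 13 rose and 2 fell adjusted over the list alone. The B cell markers Cd79b and Cd74 rose by 2.94 and 2.49. The NK and cytotoxic list split, with Ccl5 up by 3.10 and Klrd1 at -2.63.

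In total 1853 genes rose and 1655 fell in fresh nTregs against naive cells. Outside the lists, the largest rises were Lars2 by 6.24 and S100a4, a calcium-binding protein gene, by 5.39. The largest falls were Pdlim4 at -4.66, the phosphodiesterase gene Pde3b at -3.72 and Vipr1, the receptor of vasoactive intestinal peptide, at -3.54. Camera at the preset correlation placed the Treg signature upward (adjusted p = 4.95e-29), and adjusted p = 0.226 with an estimated correlation. It placed the naive list downward (adjusted p = 3.39e-08), and adjusted p = 0.320 with an estimated correlation. The TCR-induced list and cytokines (both 1.2e-06), NF-kappaB and IL-2 and STAT5 response (both 2.83e-06), checkpoint receptors (3.98e-06), helper lineage (4.33e-06) and trafficking receptors (1.23e-05) also passed upward at the preset correlation. With an estimated correlation these 7 lists had adjusted p of 0.226 to 0.277. Further lists that passed upward were proliferation (0.00161), immediate early genes (0.00258), apoptosis regulators (0.00633), B cell markers (0.00895) and YAP-TEAD target genes (0.0373, with Nt5e up by 3.22). With an estimated correlation these 5 had adjusted p of 0.277 to 0.658, and none of the 25 lists passed, the Treg signature with all 30 members called included. The few residual degrees of freedom leave that version little power. Without 1 library the counts were 1852 (WT naive), 1783 (cKO naive), 1417 (WT fresh nTreg) and 1332 (cKO fresh nTreg), and the Treg signature stayed at 30 of 30 in each. Without the WT or the cKO stimulated nTreg library they were 4599 and 4617. Rescaled to an equal FPKM sum per library, 2825 genes rose and 679 fell, as the median over all genes moved from -0.02 to 0.16. Under that scaling 30 Treg signature genes still rose and 10 naive genes still fell.

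Stimulated nTregs had more RNA of cell cycle genes and less of immediate early and NF-kappaB genes than fresh nTregs. No nTregs were cultured without stimulation. Time in culture and recovery from the sort therefore cannot be told apart from stimulation, here or in the response difference between genotypes. Of the proliferation list 23 of 25 rose (24 adjusted over the list alone), by a median of 1.31 in log2. Ccna2 rose by 2.54 (SE 0.126, adjusted p = 0.000104) and Top2a by 2.35 (SE 0.105, adjusted p = 7.7e-05), while Pcna and Tk1 did not pass over all genes. Of 15 immediate early and sorting stress genes 12 fell, the same number adjusted over the list alone. The AP-1 genes fell, with Fos at -6.01 (SE 0.131, adjusted p = 7.75e-06), Fosb at -5.17 and Junb at -4.11. The phosphatase gene Dusp1 stood at -5.42, from 366 and 461 FPKM in fresh nTregs to 7.49 and 9.94. Of 14 NF-kappaB response genes 12 fell, led by the feedback inhibitor Tnfaip3 at -5.73 (SE 0.0862, adjusted p = 1.68e-06), and Nfkb1 rose by 0.34. In the cytokine list 6 of 11 rose and 3 fell, the same counts adjusted over the list alone, without passing camera (adjusted p = 0.218). The chemokine genes Ccl3 and Ccl4 rose by 4.39 and 3.45, while Ccl5 and Cxcl10, from other lists, fell by 2.62 and 2.91. The unfolded protein and amino acid response list was divided and did not pass camera (adjusted p = 0.231), with 6 of 12 up and 3 down (7 and 3 adjusted over the list alone). Asns, the asparagine synthetase gene, rose by 4.32 and Dnajb9 fell by 2.56, and 3 of the list rose without the cKO fresh nTreg library and 4 without the cKO stimulated nTreg library. The zinc transporter gene Slc39a8 rose by 4.05, Emp1 by 4.22 and the STAT5 target Socs2 by 3.46. Nupr1 was listed at 0 in all 4 unstimulated libraries and was 32.6 and 35.2 FPKM after stimulation. Of the naive and quiescent list 13 of 17 fell again, with Dapl1 at -3.24 and Satb1 at -1.86, and Foxp1 rose by 0.31. Of 22 interferon-response genes 15 fell, with Mx1 at -2.75 and Isg15 at -2.19, while Gbp2 and Gbp3 rose by 2.40 and 1.29. In the Treg signature 16 rose (Il2ra by 2.05, Foxp3 by 0.30) and 7 fell (Areg at -3.08, Klrg1 at -2.68, Ctla4 at -1.15), with the same counts adjusted over the list alone. Tead1, a DNA-binding partner of YAP, rose by 1.04, to 1.12 and 1.22 FPKM. In the TGF-beta and activin list 6 rose, among them Acvr1c by 1.21, and 8 fell (9 adjusted over the list alone), with Bambi at -1.71. Without the WT fresh nTreg library 3 of that list fell, Acvr1c was not called, and 10 rather than 16 Treg signature genes rose.

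In total 2527 genes rose and 3061 fell with stimulation. The largest other falls were Ppp1r15a at -4.91, Sik1 at -4.73, Dtx1 at -4.53, Rgs2, a regulator of G protein signalling, at -4.36 and Dusp10 at -4.15. Camera at the preset correlation placed proliferation upward (adjusted p = 1.19e-10), and adjusted p = 0.686 with an estimated correlation. Immediate early genes (4.99e-09), naive genes (4.42e-05), NF-kappaB genes (5.24e-05) and interferon genes (0.0113) were placed downward, and their adjusted p were 0.522, 0.686, 0.522 and 0.727 with an estimated correlation. Without the WT fresh nTreg library 2895 genes were called and without the cKO fresh nTreg library 3019. Scaling set the balance of the whole comparison. Rescaled to an equal FPKM sum per library, 6848 genes rose and 1033 fell, as the median over all genes moved from -0.05 to 0.48. Under that scaling 25 proliferation genes rose, 12 immediate early, 10 NF-kappaB and 11 naive genes fell, and the interferon list had 10 falls and 6 rises. The TGF-beta and activin list turned from 6 rises and 8 falls to 11 rises and 3 falls.

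Stimulation changed the transcriptome alike in WT and cKO nTregs for most genes, with a Pearson r of 0.78 over 11522 genes between the responses of the WT and the cKO pair of libraries. The genes are not independent replicates, and 91.5% of them were within 1.5-fold. The response difference, cKO minus WT, was at least 2-fold above 0 for 100 genes and at least 2-fold below 0 for 110, without replicates or a test. The cytokine list lay above the random range (median 0.33, at percentile 99.8) but was divided, with 7 of 13 members above 0 and 6 below. Ccl3, at 0.98, was more induced in cKO, while Ifng, at 0.86, was lower after stimulation in WT (17.7 to 4.02 FPKM) and in cKO (33.2 to 15.6), with the smaller loss in cKO. Also above the random range were checkpoint receptors (median 0.29, with Lag3 at 1.11 and Pdcd1 at 0.74), glycolysis (median 0.27, 15 of 16 above 0) and proliferation (median 0.26, 21 of 25 above 0). The unfolded protein and amino acid response (median 0.26, with Creld2 at 0.95) lay there too. So did the interferon list (median 0.24, 15 of 22 above 0), most of which fell with stimulation, so that Isg15 at 1.20 marks a smaller loss in cKO and Cxcl10 at -1.01 a larger one. The naive list had a median of -0.13. The largest single differences were Amd1, Btg3 at 3.17, Rps27 at 2.89 and Ndufs5 at 2.67, which have near copies, and Snhg9, listed at 0 in both stimulated libraries. In the other direction stood AA467197 at -2.17 and Ly6c2 at -1.61. Dcpp1, Dcpp2 and Defa4 also differed but are listed at 0 in 1 or more of the 4 libraries. Rescaled to an equal FPKM sum per library, 124 genes were above and 377 below, as the median over all genes moved from 0.04 to -0.11, and the cytokine and proliferation medians were 0.22 and 0.11.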

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

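The tests of explanations, the splits and the sums over copies in this part were chosen after the results were seen, while the gene lists, their placement among random lists and the scalings they draw on were planned. A pair of genes had genotype differences of opposite sign in different populations, which were not tested. Amd1 stood at -3.97 in naive cells, 0.00 in fresh nTregs and 3.66 in stimulated nTregs in log2, a spread of 7.63, and its near copy Amd2 makes up the difference in the sum. Btg3 stood at -0.00, -2.14 and 1.03, a spread of 3.17 between fresh and stimulated nTregs, and its sum with the near copy Gm7334 differed by -0.05 in fresh and 0.32 in stimulated nTregs.

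The 42 genes called for genotype across the populations were weighed against explanations. Of the 33 left without histone, H2 and small RNA genes and Erdr1, which has no coordinates, 15 had another called gene within 5 Mb, where random draws gave 5.63 on average and 25 of 10000 gave 15 or more, with Oip5os1, Jmjd7, Ehd4, Ttbk2, Sord and Slc28a2 on chromosome 2 between 119594296 and 122461152 and Sgk1 with H60b on chromosome 10, which is consistent with stretches of another strain's or donor's sequence carried in 1 of the genotypes. Sequence around Yap1 alone cannot account for them, since 40 of the 41 with coordinates lie outside 5 Mb of it. Fragments shared between near copies cannot account for the 27 of the 41 searched that have none among annotated transcripts. For the 14 with a near copy, Eno1b among them, and for Ndufs5-ps, which could not be searched, shared fragments remain open. A loss of YAP in the T cells cannot be told apart from background differences here, because Yap1 is listed at 0 in 4 of 6 libraries, was not lower in cKO in the others, and each genotype may come from few mice. Of the 10 splits of the 6 libraries into groups of 3, the real one gave 42 genes and the highest other 6, and 1 gave 42 or more, a share that is never under 0.1 with 10 splits; the 3 others that keep a library of each population per side, as the real one does, gave 1, 0 and 0, and 4 such splits are too few as well.

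The higher medians of the cytokine, helper lineage and proliferation lists in stimulated cKO nTregs were weighed as well. These lists stayed at least 0.361 above the median of all genes under the 2 other scalings. That measure cannot test scaling, because rescaling a library moves nearly all genes alike. The plain medians of proliferation, cytokines and helper lineage were 0.54, 0.51 and 0.375 with rescaling by the median of ratios. At an equal FPKM sum per library they were 0.41, 0.38 and 0.29, so neither scaling removed the differences. CD8 T cells or NK cells that passed the CD4+ CD25 high sort gate, which is set against them, cannot be told apart from genes that nTregs themselves express, because the NK and cytotoxic list lay at percentile 98.7 of random lists, with 5 of 5 members higher, while the CD8 list, with Cd8b1 alone, lay at percentile 67.7. In fresh nTregs, which were not cultured, these lists also lay above the random range (proliferation 0.32, helper lineage 0.20, cytokines 0.20). A difference that arose in culture would not account for those, although the cytokine median there changed sign at an FPKM minimum of 5. With 1 library per genotype, single cultures, strain or donor background, the sex mix of the pools and YAP loss cannot be told apart in stimulated nTregs.

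The low Xist in the cKO nTreg libraries was weighed too. In fresh and stimulated nTregs, 16 of 16 differences of Y-linked genes (Ddx3y, Eif2s3y, Kdm5d, Uty) and of genes that escape X inactivation went the way that fewer female cells in the cKO pools would give, so a different share of female mice is a candidate explanation. In fresh nTregs an effect on Xist alone would leave Y-linked genes in place, and their median lay at percentile 100 of random lists. In stimulated nTregs it lay at percentile 90.4, inside the random range, so an effect on Xist alone cannot be told apart there.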

How the results depend on the processing

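Removing short features in the single-library comparisons and leaving transcripts unsummed were chosen after the results were seen; the other alternatives were planned. For genes named with a limma test, 4649 values kept direction and side of the threshold, 190 lost the call, 19 gained it and 4 reversed; for genes without a test 2494 stayed within the set range and 96 moved; for list medians 640 stayed within the set range, 3 moved and 2 reversed, where only medians outside the random range count as reversed. Inside it 38 more of the 645 changed sign, 15 of them at an equal FPKM sum per library. The counts of genes 2-fold apart in naive cells, fresh nTregs, stimulated nTregs and the response (125, 112, 211 and 210) became 274, 275, 494 and 607 with a pseudocount of 0.1, which admits low genes by construction, and 46, 45, 85 and 59 with a pseudocount of 5, which shrinks low genes by construction. At an FPKM minimum of 5, with fewer genes compared, naive cells gave 72 and the response 104. Rescaled to an equal FPKM sum per library, stimulated nTregs gave 473 and the response 501, and the cause was not tested. A 3-fold threshold gave 43, 44 and 58. Unsummed transcripts gave 873, 869, 1232 and 1713, and the cause was not tested. The 42 genotype genes became 17 with a pseudocount of 5 and 4 with no FPKM minimum; fresh nTreg against naive went from 3508 to 2183 with no minimum, where 21218 rather than 11224 genes were tested, and the cause was not tested. Leaving out 1 library, which leaves fewer residual degrees of freedom and assumes that the lone sample varies like the others, gave 14 to 54 genotype genes, 1332 to 4617 for fresh nTreg against naive and 2895 to 5319 for stimulated against fresh nTreg. At an FPKM minimum of 5, 2 medians reversed: TCR-induced activation, median log2 difference, genotype difference in naive CD4 T cells (-0.0303) and cytokines, median log2 difference, genotype difference in fresh nTregs (-0.0183). The reversed genes were Xist in fresh nTreg against naive (1.06 without the cKO naive library, against -1.07 without the WT naive library) and, stimulated against fresh under an equal FPKM sum, Kdm5d (0.447), Pecam1 (0.0070) and Uty (0.153); the cause was not tested for Xist. No paired analysis was possible by replicate number because the groups hold 1 replicate each, although population was a term of the model and the genotype contrast lies within populations. Depth limits Yap1 and other genes near 0.1 FPKM, where 1 fragment decides a value.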

Other observations

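The genes below were chosen after their values were seen, and no explanation for them was tested. Short RNA genes outside the naming rule showed some of the sharpest contrasts between the genotypes. Snora41, a small nucleolar RNA gene with a near copy of 97.7% identity over its whole transcript, was listed at 0 in the 3 WT libraries and was 99.2, 135 and 132 FPKM in cKO naive cells, fresh nTregs and stimulated nTregs. Mir8118, a micro RNA gene, was 27.4, 29.0 and 33.7 in WT and listed at 0 in the 3 cKO libraries.

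Several replication-dependent histone genes differed between genotypes in opposite directions. H2bc13, H2bc12 and H4c9 were at least 2-fold higher in cKO in all 3 populations, with H2bc13 at 112 against 17.7 FPKM in stimulated nTregs, while H2bc15 was lower in all 3 (60.2 against 89.2 in stimulated nTregs) and H4c11 was lower in naive cells (1.56 against 8.22). The H2b genes among them have 9 to 12 near copies each among the annotated genes. Lars2, a mitochondrial leucyl-tRNA synthetase gene, was 10.7 and 9.74 FPKM in naive cells, 1285.8 and 555 in WT and cKO fresh nTregs and 1081.5 and 584 after stimulation.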
